A study of Mus musculus with 24 samples.

How the data were processed

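RNA was measured in epididymal white fat of 24 male C57Bl/6 mice, 6 in each of 4 groups given by the labels: conventional or germ-free mice fed lard or menhaden fish oil. Per the labels' protocols, total RNA was isolated with a kit for lipid-rich tissue, and 250 ng from each mouse were amplified, biotinylated and hybridised to a one-colour Affymetrix array. The deposited values are log2 expression values, 1 per probe set and mouse, made with RMA per the submitters' processing notes. RMA corrects background, normalizes quantiles between arrays and combines the probes of each probe set, which brings the distributions of the arrays close before any comparison. Its version, the annotation used and the scanning dates are not given in the sources used here, and no batch could be tested. The values lay between 2.19 and 14.59 with array medians from 7.09 to 7.20, and 0 pairs of arrays held identical values. The medians were not fully alike between groups: 7.17 to 7.20 in fish oil-fed germ-free mice and 7.10 to 7.13 in fish oil-fed conventional mice. The number of arrays limits the precision, and low signals are compressed towards the background, which understates changes of weakly expressed genes.

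Probe sets were named through a table of platform annotation. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none. Symbols were updated by Entrez ID in a reference gene table (GRCm38.p6, used for names only), in which 21698 of the 21789 were found, and no coordinates were used. Probe sets with several symbols or none were left out of the main comparisons. For a gene with several probe sets, the one with the highest mean over all arrays was used, which left 19938 genes.

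Each comparison was a contrast in a fit of the 4 group means to all 24 arrays, with lmFit and eBayes in limma 3.58.1 under R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over the 19938 genes within a comparison, two-sided, with a threshold of 0.05, and every adjusted p of a gene comes from limma. The 5 comparisons were lard over fish oil in conventional and in germ-free mice, conventional over germ-free in lard-fed and in fish oil-fed mice, and the interaction, which is the effect of bacterial status with lard minus that with fish oil. The effects of each factor were correlated across genes between the levels of the other factor, with a jackknife over mice for the error. Changes are differences of mean log2 values. Figures were drawn with matplotlib 3.10.9 and tables handled with numpy 2.4.6 and pandas 2.3.3 under python 3.11.15.

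Comparisons, tests, alternatives, the rule for named genes and 32 gene lists were set before the data were examined. The lists cover immune, adipose, vascular and neighbouring cell types, lipid and energy metabolism, inflammation, matrix, clock, stress and early response genes, and 11 genes are in more than 1 list. Lists were tested with camera against all other genes with a preset correlation of 0.01, adjusted over the 31 lists with at least 5 measured genes; of the red blood cell list only 3 genes were measured, and it was not tested. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance without setting them against other genes, were alternatives. For each list the genes past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone. Lists of 25 liver and 20 intestinal epithelium transcripts were added after seeing the data.

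Genes named in the text come from a rule set beforehand: for each comparison, the 10 largest rises and the 10 largest falls past the threshold, leaving out clone, predicted, receptor segment, olfactory and similar names; up to 4 members of each list with the largest changes past the threshold; and a panel of 40 genes of fat, lipid and immune biology given where it bore on a comparison. Not all genes that the rule allows are named. Entpd4, Rab4a and Wdfy1, Nnt with lard and Lrmda in the interaction fall outside it and were chosen after their values were seen.

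Alternatives were median centring of each array, repeated quantile normalization, a filter that left out genes under the 40th percentile of mean value, the mean of all probe sets of a gene, array weights, an eBayes trend with robust priors, fits of only the groups compared, the mouse number as a block, all probe sets, a threshold of at least 1.5-fold, and leaving out each mouse. Added after seeing the data were fits without lard-fed conventional mice 5 and 6, without lard-fed germ-free mice 2, 4 and 5, and with the mean of the liver transcripts as a covariate. Random splits of the mice into groups of the same sizes, 100 for each comparison, gave the counts that other groupings reach.

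The test was tested on simulated data for the same 19938 genes, with 100 genes changed by 1 log2 and 100 by 0.5. For lard against fish oil in conventional mice 100% and 81% were recovered, with 5.7% false among the calls. For conventional against germ-free in lard-fed mice the values were 100%, 83% and 5.2%, and for the interaction 93%, 49% and 4.1%. Of 31 simulated lists in the first comparison, the 3 shifted by 0.5 log2 were called and 0 others. The simulated noise was independent between genes, so these rates do not cover genes that move together. In the real data, other splits of the mice gave a median of 12 lists in this comparison.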

Results

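Gene expression was measured in the epididymal white fat of 24 male C57Bl/6 mice, in 4 groups of 6 that differed in 2 factors. Epididymal white fat is a visceral fat depot that lies along the epididymis, and it takes up immune cells as the depot grows. Mice were fed for 11 weeks, from 11 weeks of age, on diets with 45% of energy from fat, which came either from lard, rich in saturated and monounsaturated fatty acids, or from menhaden fish oil, rich in long-chain omega-3 fatty acids. Mice on each diet were either conventional, with a normal microbiota, or germ-free, raised without microbes, and were fasted for 4 h before sampling. Each mouse gave 1 one-colour Affymetrix array, so p-values measure the spread between mice, and the number of arrays limits the precision. The deposited values are log2 signals of 35556 probe sets, with array medians from 7.09 to 7.20 and correlations between arrays of the same group from 0.980 to 0.997. A total of 19938 named genes were tested.

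On the first principal component, which held 49.5% of the variance, all 12 fish oil-fed mice lay between -36.2 and -11.8. The lard-fed germ-free mice lay from 18.7 to 46.1. Lard-fed conventional mice fell apart: mice 1 to 4 lay from -4.62 to 8.92, and mice 5 and 6 at 33.0 and 42.1, among the germ-free mice. The mean of the lipid-associated macrophage markers was 11.84 log2 in mouse 5 and 11.91 in mouse 6, against 10.89 to 11.20 in mice 1 to 4. Their macrophage marker means were 11.15 and 11.04 against 10.46 to 10.75, and their mature adipocyte marker means 12.11 and 12.17 against 12.45 to 12.53. A list of 25 liver transcripts, drawn up after the data were seen, averaged 8.25 ± 0.57 log2 (SD, n = 6) in fish oil-fed germ-free mice, against 6.46 ± 0.52 in fish oil-fed conventional, 6.74 ± 0.51 in lard-fed conventional and 6.45 ± 0.49 in lard-fed germ-free mice. A list of 20 intestinal epithelium transcripts, also drawn up after the data were seen, averaged 9.29 log2 in lard-fed germ-free mouse 4, 6.79 in mouse 5 and 6.63 in mouse 2. In the same group mouse 6 had 6.35 and mice 1 and 3 had 5.87 and 5.99. All mice of the other 3 groups lay from 5.85 to 6.23.

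**Figure D1:**
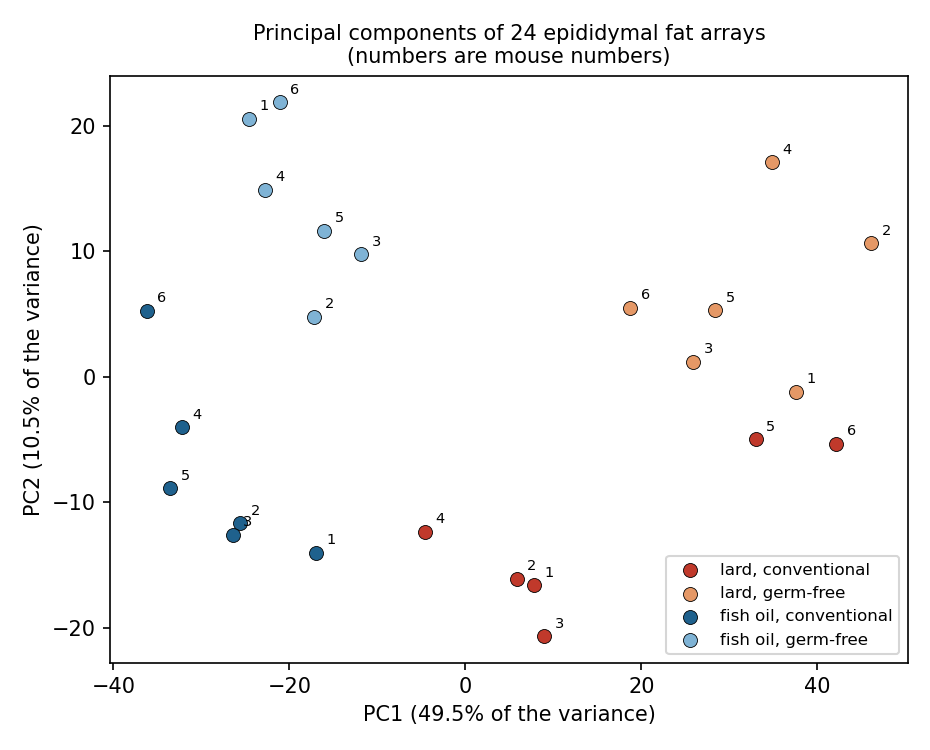
Each point is 1 mouse, placed by its scores on the first (49.5% of the variance) and second (10.5%) principal components of the log2 values, with the colour giving the group of 6. Lard-fed conventional mice 5 and 6 lie at 33.0 and 42.1 on the first component, inside the lard-fed germ-free range of 18.7 to 46.1.

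The first comparison asked how the fat source of the diet changed the fat depot of mice with a normal microbiota. With lard, genes of macrophages, antigen presentation, Toll-like receptor signalling, cell division and matrix were higher than with fish oil, and genes of oxidative phosphorylation, fatty acid synthesis and insulin signalling were lower. Of these lists only antigen presentation passed with an estimated correlation. The RNA came from the whole depot, so the lists describe a mixture of cells. Here and below, a changed share of a cell type was not told apart from a change within cells. Gpr50, an orphan receptor related to the melatonin receptors, had the largest rise, from 5.90 ± 0.77 log2 with fish oil to 10.73 ± 0.79 with lard (SD, n = 6), a log2 change of 4.83 ± 0.38 (SE, limma adjusted p = 4.1e-09). Lipf, gastric lipase, rose by 3.27, Tnip3, an inhibitor of NF-kappaB signalling, by 2.56, Ubd, a cytokine-induced ubiquitin-like protein, by 2.40, and Timp1, an inhibitor of matrix metalloproteinases, by 2.31. Acsm3, a medium-chain acyl-CoA synthetase, had the largest fall, with a log2 change of -2.87. It was followed by the carboxylesterase Ces1f (-2.82), Fam13a, a gene of adipocyte insulin signalling (-2.58), and the glutathione transferase Gsta4 (-2.56).

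In all, 6178 genes differed by diet in conventional mice, 3076 higher and 3102 lower with lard, and 1627 of them by at least 1.5-fold. Without lard-fed conventional mice 5 and 6 the count was 4442, of which 4190 were among the 6178. Among 20 macrophage markers, 16 were higher, 2 lower and 2 not past the threshold (adjusted p = 0.231 with an estimated correlation), with the same counts adjusted over the list alone; Cd68 rose by 1.38 and Adgre1, which encodes F4/80, by 1.37. Lipid-associated macrophages cluster around dying adipocytes, and 15 of their 17 markers were higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.231 with an estimated correlation). Among these were Atp6v0d2, a subunit of the lysosomal proton pump (2.03), Trem2, a lipid-sensing receptor (2.01 ± 0.29, adjusted p = 9.7e-06), and Itgax, which encodes CD11c (1.93). The 2 lard-fed conventional mice with the highest means of these lists were mice 5 and 6, as given above, and their proliferation list means were 8.72 and 9.01 against 7.93 to 8.55 in mice 1 to 4. Proliferation genes were higher in 17 of 17, as they were adjusted over the list alone (adjusted p = 0.106 with an estimated correlation), among them the mitotic genes Bub1 (1.61), Ccnb2 (1.48) and Cdk1 (1.34). Antigen presentation by MHC class II was the list whose call held with an estimated correlation (adjusted p = 0.0208): 12 of 12 members were higher, also adjusted over the list alone, with H2-DMa at 1.47 ± 0.09 (adjusted p = 1.9e-10) and Cd74, the invariant chain, at 1.13. Means of this list were 10.10 and 10.07 in mice 5 and 6 against 9.81 to 9.97 in mice 1 to 4.

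Toll-like receptors recognise microbial products and, in part, host molecules. Of 26 genes of this pathway, 20 were higher with lard in conventional mice and 0 lower, or 20 and 1 adjusted over the list alone (adjusted p = 0.0837 with an estimated correlation). Tlr13 rose by 1.70, Tlr8 by 1.62 and the adaptors Myd88 and Ticam1, which encodes TRIF, by 0.47 and 0.42, while Tlr4, the lipopolysaccharide receptor, differed by 0.20 (adjusted p = 0.13). Cytokines and chemokines were higher in 17 of 33 and lower in 2, or 19 and 3 adjusted over the list alone (adjusted p = 0.231 with an estimated correlation). Il1rn, the interleukin-1 receptor antagonist, rose by 2.16, Ccl2, a monocyte attractant, by 1.47 ± 0.28 (adjusted p = 0.0002) and Tnf by 0.65, and Il6 differed by 0.09 (adjusted p = 0.73). Saa3, an acute-phase protein made by fat and macrophages, rose by 1.95 and Lcn2, an iron-scavenging antimicrobial protein, by 1.34; of the 19 genes of their list 7 were higher and 3 lower, or 8 and 3 adjusted over the list alone (adjusted p = 0.389 with an estimated correlation). Collagen and matrix genes were higher in 21 of 27 and lower in 1, the same adjusted over the list alone (adjusted p = 0.0958 with an estimated correlation), with Postn, periostin, at 0.92 and Col1a1 at 0.74. Part of this rise lay in lard-fed conventional mice 5 and 6, with list means of 10.91 and 10.86 against 10.40 to 10.56 in mice 1 to 4. Interferon-stimulated genes were higher in 20 of 31 and lower in 1, or 21 and 2 adjusted over the list alone (adjusted p = 0.231 with an estimated correlation).

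Oxidative phosphorylation genes encode the respiratory chain, and with lard 26 of 27 were lower in conventional mice, as they were adjusted over the list alone (adjusted p = 0.0958 with an estimated correlation). Ndufa5, of complex I, had a change of -1.28 and Sdhb, of complex II, of -0.85. The lowest list means of the lard-fed conventional mice were those of mice 5 and 6, 11.13 and 11.09 against 11.36 to 11.48. Fatty acid synthesis and desaturation genes were lower in 12 of 22 and higher in 2, or 12 and 3 adjusted over the list alone (adjusted p = 0.443 with an estimated correlation). Changes were -2.02 for Thrsp, a regulator of lipogenesis, -1.87 for Acaca, acetyl-CoA carboxylase, and -0.75 for Fasn, fatty acid synthase. The desaturases Scd1 and Fads2 differed by 0.01 and 0.02 (adjusted p = 0.93 and 0.89). Insulin signalling and glucose handling genes were lower in 14 of 23 and higher in 1, or 14 and 2 adjusted over the list alone (adjusted p = 0.106 with an estimated correlation). Among them were Pck1, an enzyme of gluconeogenesis and glyceroneogenesis (-1.88), the glucose transporter Slc2a4 (-1.09) and Irs1 (-1.07). Mature adipocyte markers were lower in 13 of 17 and higher in 1, or 14 and 1 adjusted over the list alone (adjusted p = 0.346 with an estimated correlation), with list means of 12.11 and 12.17 in mice 5 and 6 against 12.45 to 12.53 in mice 1 to 4. Lep, leptin, rose by 0.48 and Ffar4, a receptor for omega-3 fatty acids, fell by 0.95. Adipoq, adiponectin, fell by 0.46 (adjusted p = 0.0052), a call that ended without mice 5 and 6 (adjusted p = 0.0706). Mesothelial markers, of the cell layer that covers the depot, were lower in 11 of 14, or 12 adjusted over the list alone (adjusted p = 0.346 with an estimated correlation), with Muc16 at -1.03. Each named gene past the threshold had 6 of 6 lard-fed mice on the same side of the fish oil mean. Of 31 lists, 19 passed with camera's preset correlation and 1 with an estimated one.

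**Figure D2:**
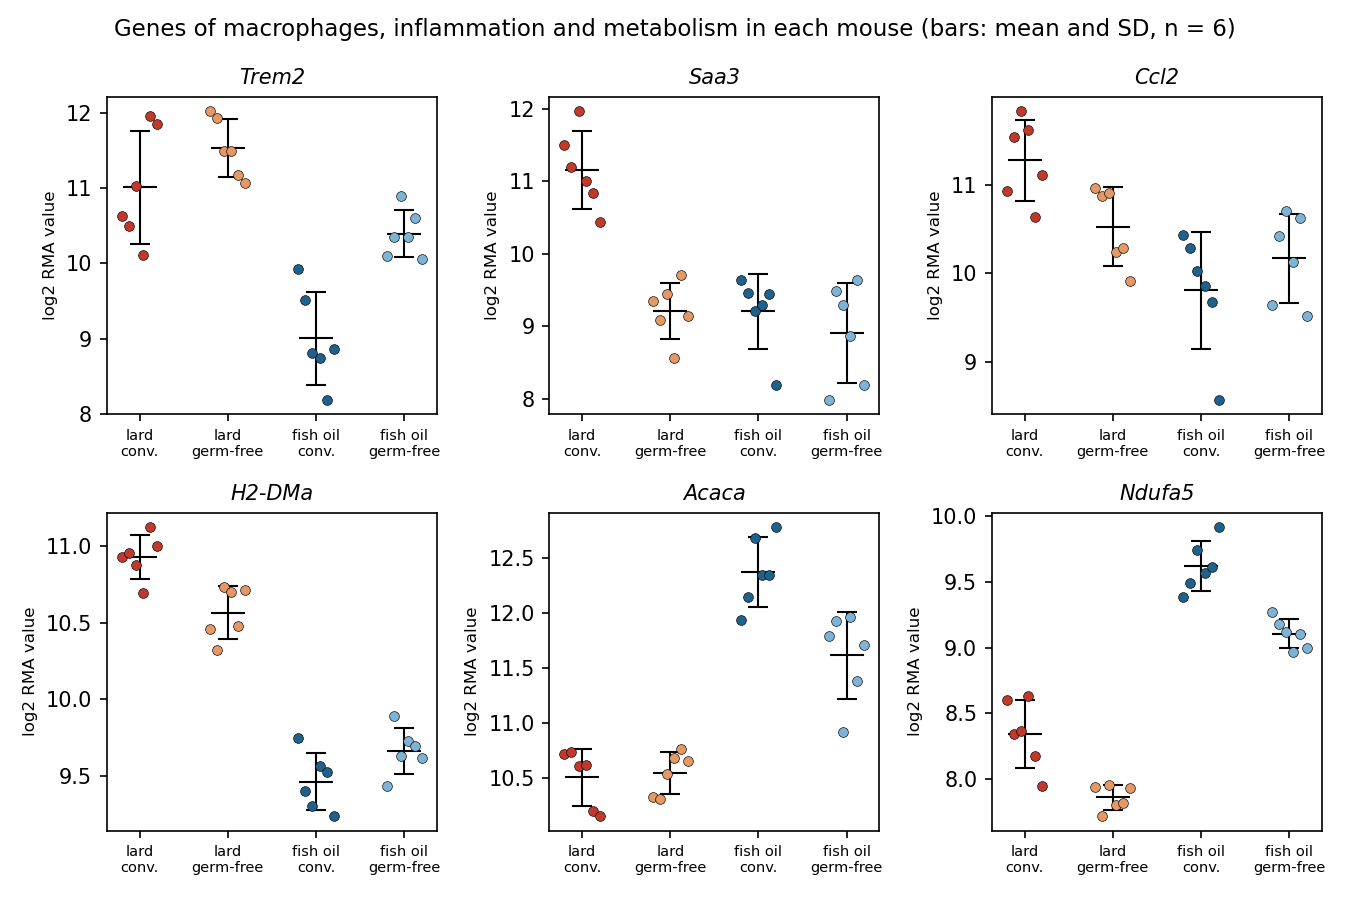
Log2 RMA values of 6 genes of macrophages, inflammation and metabolism in each mouse (points), with the mean and SD of each group of 6 (bars). Saa3 averages 11.16 ± 0.53 in lard-fed conventional mice and 8.91 to 9.21 in the other 3 groups, whereas Ndufa5 is lower with lard under both bacterial states.

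The same diets were then compared in germ-free mice, which asks what the fat source did where no microbes were present. Macrophage, proliferation, Toll-like receptor, cholesterol synthesis and matrix genes were again higher with lard and oxidative phosphorylation genes lower, while Saa3, Lcn2 and Ccl2 did not pass the threshold. With an estimated correlation 0 of these lists passed, as given below. Gpr50 rose by 4.89 ± 0.38 (SE, limma adjusted p = 6e-09) from 7.11 ± 0.94 log2 with fish oil (SD, n = 6). Oxtr, the oxytocin receptor, rose by 3.34, Tnip3 by 2.74 and Lipf by 2.68. Fam13a, Gsta4 and Acsm3 had changes of -3.16, -2.48 and -2.34. Among the largest falls were transcripts made by the liver, with changes of -4.36 for Serpina1c, an antitrypsin, -3.78 for Alb, albumin, and -3.01 for Fgb, the fibrinogen beta chain. Of the 25 liver transcripts, 23 were lower with lard in germ-free mice and 0 higher, with a median change of -1.67.

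A total of 9468 genes differed by diet in germ-free mice, 4072 higher and 5396 lower with lard, and 1985 of them by at least 1.5-fold. With each array centred on its median the split was 4808 higher and 3313 lower. Repeated quantile normalization gave 4008 higher and 4002 lower, and the low-value filter 3794 and 3260. Without lard-fed germ-free mice 2, 4 and 5 the count was 5278, with 2891 higher and 2387 lower. With the liver transcript mean as a covariate the count was 6419, of which 5172 were among the 9468. Macrophage markers were higher in 15 of 20 and lower in 3, the same adjusted over the list alone (adjusted p = 0.515 with an estimated correlation), with Adgre1 at 1.76 ± 0.21 (adjusted p = 9.5e-07) and Csf1r, the macrophage growth factor receptor, at 1.29. Lipid-associated macrophage markers were higher in 8 of 17 and lower in 1, the same adjusted over the list alone (adjusted p = 0.829 with an estimated correlation). Itgax rose by 1.35 and Trem2 by 1.14. With the liver transcript mean as a covariate, the calls of Itgax (1.05, adjusted p = 0.12) and Trem2 (0.70, adjusted p = 0.251) ended. So did those of Acsm3 (-1.25, adjusted p = 0.0633), Acaca (-0.62, adjusted p = 0.0577) and Pck1 (-0.97, adjusted p = 0.11). All 17 of 17 proliferation genes were higher, also adjusted over the list alone (adjusted p = 0.341 with an estimated correlation), with Bub1 at 1.73 and Mki67 at 1.58. Cholesterol synthesis genes were higher in 12 of 20 and lower in 0, or 13 and 0 adjusted over the list alone (adjusted p = 0.515 with an estimated correlation); Lss, lanosterol synthase, rose by 1.24 and Nsdhl by 0.89. In conventional mice 10 of these 20 were higher with lard and 2 lower, or 11 and 2 adjusted over the list alone (adjusted p = 0.478 with an estimated correlation).

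Toll-like receptor genes were higher with lard in 18 of 26 and lower in 2 in germ-free mice, the same adjusted over the list alone (adjusted p = 0.341 with an estimated correlation), with Tlr1 at 1.56 and Tlr8 at 1.49. Ticam1 differed by -0.05 (adjusted p = 0.6) and Saa3 by 0.30 (adjusted p = 0.38). Lcn2 differed by -0.12 (adjusted p = 0.74), or by -1.35 with the liver covariate, which passed (adjusted p = 0.0137). Ccl2 differed by 0.36 (adjusted p = 0.28), and Il1rn rose by 1.74. Cytokines and chemokines were higher in 8 of 33 and lower in 9, or 8 and 10 adjusted over the list alone, and this list did not pass even with the preset correlation (adjusted p = 0.813; 0.954 with an estimated correlation). MHC class II genes were higher in 7 of 12 and lower in 0, or 8 and 0 adjusted over the list alone (adjusted p = 0.341 with an estimated correlation), with H2-DMa at 0.90 and Cd74 at 0.65. Oxidative phosphorylation genes were lower in 23 of 27 and higher in 1, the same adjusted over the list alone (adjusted p = 0.396 with an estimated correlation). Ndufa5 fell by 1.25, and Cox4i1, of complex IV, fell by 0.86. Fatty acid synthesis genes went both ways, 4 of 22 higher and 8 lower, the same adjusted over the list alone, with no call for the list by camera (adjusted p = 0.886; 0.955 with an estimated correlation). Scd2 rose by 1.62, while Thrsp fell by 1.67 and Acaca fell by 1.07. Matrix genes were higher in 18 of 27 and lower in 1, or 20 and 1 adjusted over the list alone (adjusted p = 0.341 with an estimated correlation), with the gelatinase Mmp2 at 1.56 and Lox, a collagen crosslinker, at 1.20. Insulin signalling and glucose handling genes were lower in 10 of 23 and higher in 3, or 11 and 3 adjusted over the list alone, with no call for the list by camera (adjusted p = 0.287; 0.829 with an estimated correlation) and 1 by fry (adjusted p = 0.0029); Pck1 fell by 1.48 and Irs1 fell by 1.28. Zg16, an intestinal goblet cell protein, rose by 2.36 (adjusted p = 0.0056), a call that ended without lard-fed germ-free mice 2, 4 and 5 (0.54, adjusted p = 0.124). Each named gene past the threshold had 6 of 6 mice on the same side of the other diet's mean. Of 31 lists, 11 passed with the preset correlation and 0 with camera's estimated one, where 4 had an unadjusted p under 0.05, and fry called 15.

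Across the 19938 genes, the diet effect in conventional mice and that in germ-free mice, which share no mice, had a Pearson correlation of 0.734 (jackknife SE 0.0649, leaving out mice) and a Spearman correlation of 0.643; genes are not independent replicates. With the liver transcript mean as a covariate the Pearson correlation was 0.477. That fit has a single slope per gene. Mean liver values with lard and fish oil were 6.74 and 6.46 log2 in conventional mice, and 6.45 and 8.25 in germ-free mice. Errors of the slope thus enter both diet effects with opposite signs, which by itself pushes their correlation down. A total of 2226 genes were higher with lard under both bacterial states, where independent lists of these sizes would share 628.2, and 1964 were lower under both, where independent lists would share 839.5. Another 96 were called in opposite directions.

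**Figure D3:**
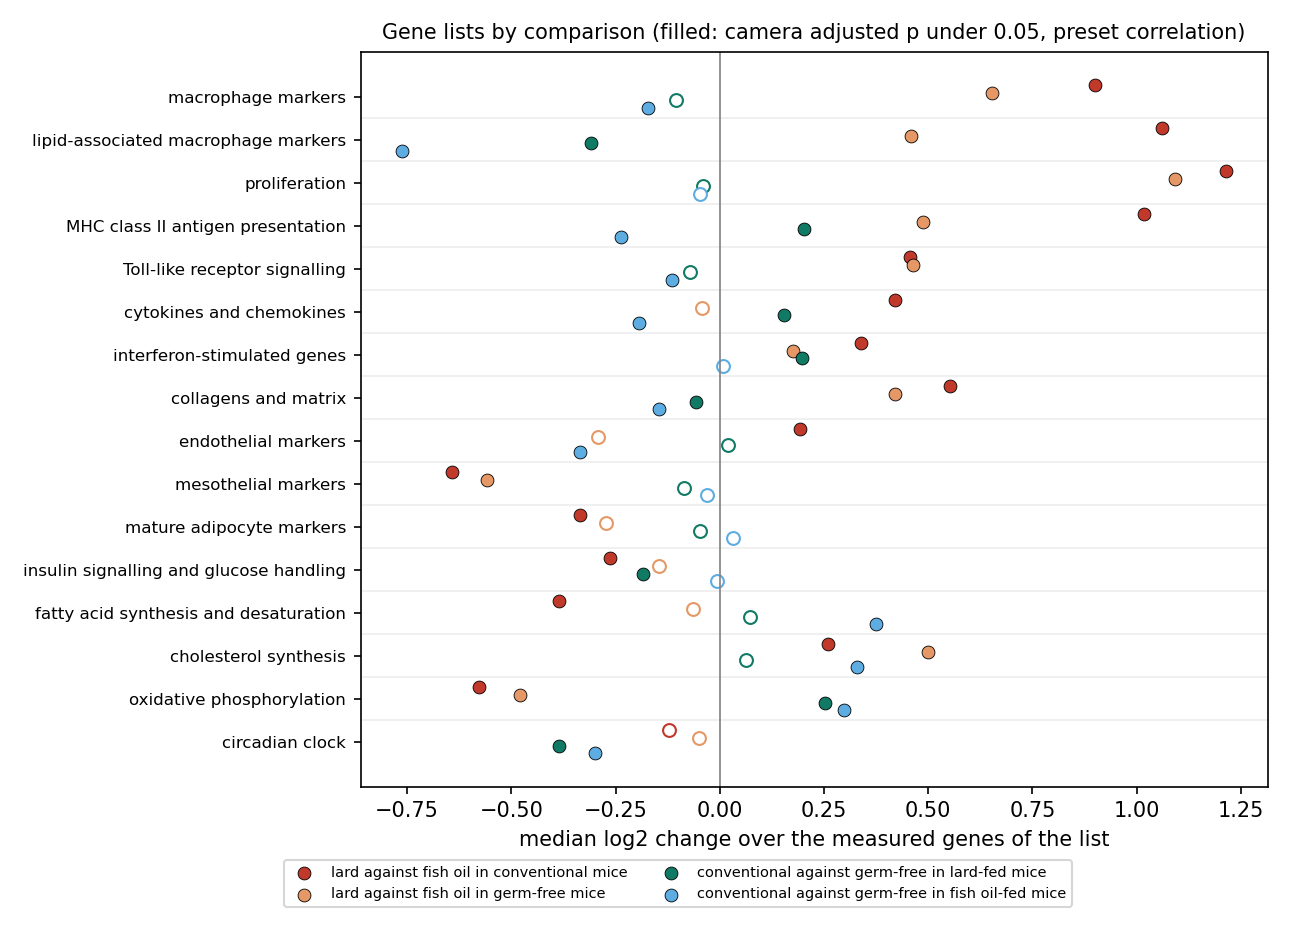
Median log2 change over the measured genes of 16 gene lists (horizontal axis) in the 4 comparisons (colours), filled where camera's adjusted p with the preset correlation passed 0.05. The proliferation list has its median at 1.22 and 1.09 for lard over fish oil in conventional and germ-free mice, and at -0.04 and -0.05 for conventional over germ-free with lard and with fish oil.

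The third comparison asked how the fat depot differed between conventional and germ-free mice fed lard. The design does not separate bacterial status from the mouse colony, here or with fish oil. Conventional mice had higher levels of some acute-phase (4 of 19), cytokine and chemokine (6 of 33) and interferon-stimulated genes (8 of 31) and of 19 of 27 oxidative phosphorylation genes than germ-free mice, and lower levels of 7 of 17 circadian clock genes. None of these lists passed with an estimated correlation (adjusted p from 0.502 to 0.736). Saa3 averaged 11.16 ± 0.53 log2 in conventional and 9.21 ± 0.39 in germ-free mice (SD, n = 6), a change of 1.94 ± 0.28 (SE, adjusted p = 0.00028). Lcn2 was higher by 1.13 ± 0.29 (adjusted p = 0.0097), the monocyte attractant Ccl8 by 1.45 and Ifitm6, an interferon-induced transmembrane protein, by 1.28. The interferon-induced chemokine Cxcl10 was higher by 1.08, and S100a8, a calprotectin subunit of neutrophils and macrophages, by 1.02. Rnase2a, an eosinophil-type ribonuclease, was higher by 2.66 ± 0.88 (adjusted p = 0.04) in 5 of 6 conventional mice, a call that ended when any of 7 of the 12 lard-fed mice was left out. Lrmda, a melanocyte differentiation gene, was lower in conventional mice, with a change of -2.22 ± 0.10 (adjusted p = 4.5e-13), as were Inmt, a methyltransferase, and Oxtr (-1.24). Gpr50 had a change of -1.27 (adjusted p = 0.0244), a call that ended when any of 4 single mice was left out.

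A total of 3240 genes differed, 1749 higher and 1491 lower in conventional mice, and 294 of them by at least 1.5-fold. Without the 3 lard-fed germ-free mice with the highest intestinal transcripts, mice 2, 4 and 5, the count was 177 and 20 of the 33 named calls ended. Many of the lost calls kept changes about as large, such as Lcn2 (1.14), Ccl8 (1.30), Gpr50 (-1.25), Mmp2 (-0.70) and Klrg1 (0.70). Without lard-fed conventional mice 5 and 6 the count was 5079. The intestinal transcripts Fabp2, a fatty acid-binding protein (-2.47), Sis, sucrase-isomaltase (-2.07), and Zg16 (-2.04) were among the largest falls. Without mice 2, 4 and 5 their changes shrank to -0.34, -0.17 and -0.21, and the calls ended. Fabp2 ranged from 4.60 to 12.42 log2 over the 6 germ-free mice. Of the 20 intestinal transcripts, 4 were lower in conventional mice and 0 higher.

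Acute-phase and antimicrobial genes were higher in 4 of 19 and lower in 0, or 8 and 0 adjusted over the list alone (adjusted p = 0.681 with an estimated correlation). Cytokines and chemokines were higher in 6 of 33 and lower in 0, as they were adjusted over the list alone (adjusted p = 0.736 with an estimated correlation), and Ccl2 differed by 0.75 (adjusted p = 0.066), or by 0.95 without mice 5 and 6 (adjusted p = 0.022) and by 0.94 with the liver covariate (adjusted p = 0.0041). Ccl2 also passed with array weights, the replicate block, the low-value filter and the fit of only these groups (adjusted p = 0.00777, 0.0202, 0.0446 and 0.0481). Interferon-stimulated genes were higher in 8 of 31 and lower in 1, or 9 and 1 adjusted over the list alone (adjusted p = 0.736 with an estimated correlation), with Zbp1, a nucleic acid sensor, at 0.67 and Rtp4 at 0.64. MHC class II genes were higher in 5 of 12, or 6 adjusted over the list alone, and lower in 0 (adjusted p = 0.681 with an estimated correlation), with the costimulator Cd86 at 0.46 and H2-DMa at 0.36. NK cell markers were higher in 5 of 11, or 6 adjusted over the list alone, and lower in 0 (adjusted p = 0.681 with an estimated correlation), with the receptor Klrg1 at 0.70. Oxidative phosphorylation genes were higher in 19 of 27 and lower in 2, the same adjusted over the list alone (adjusted p = 0.681 with an estimated correlation), with Cox5a at 0.56 and Ndufa9 at 0.48. Conventional mouse 6, with a list mean of 11.09, lay within the germ-free range, which ran from 10.97 to 11.125. Mouse 5, at 11.133, lay just above it, and mice 1 to 4 at 11.36 to 11.48. The cholesterol synthesis gene Ebp was higher by 0.51.

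Clock genes were lower in conventional mice in 7 of 17 and higher in 1, or 9 and 2 adjusted over the list alone (adjusted p = 0.502 with an estimated correlation). Dbp, an output gene of the clock, had a change of -0.89, Bhlhe40 of -0.73 and Per2 of -0.71. Arntl, the partner of CLOCK, was higher by 0.52 (adjusted p = 0.0374), a call that ended when any of 7 single mice was left out. Lipid-associated macrophage markers were lower in 2 of 17 and higher in 1, or 3 and 1 adjusted over the list alone (adjusted p = 0.736 with an estimated correlation). Itgax differed by -0.87 (adjusted p = 0.057) and Adgre1 by -0.56 (adjusted p = 0.073); without mice 5 and 6 both passed, at -1.41 (adjusted p = 0.000236) and -0.93 (adjusted p = 0.00027). Both also passed with array weights (-1.145 and -0.702, adjusted p = 0.00254 and 0.0046) and the low-value filter (adjusted p = 0.0389 and 0.0492), and Adgre1 with quantile normalization (adjusted p = 0.0449). Toll-like receptor genes were lower in 4 of 26 and higher in 0, as they were adjusted over the list alone, with no call for the list by camera (adjusted p = 0.192; 0.736 with an estimated correlation), and Map3k7, the kinase TAK1, had a change of -0.54. Matrix genes were lower in 6 of 27 and higher in 0, the same adjusted over the list alone (adjusted p = 0.736 with an estimated correlation), with Mmp2 at -0.70 in 5 of 6 mice. Adipoq and Lep differed by 0.06 and 0.01 (adjusted p = 0.81 and 0.96), and without mice 5 and 6 Adipoq passed at 0.30 (adjusted p = 0.0129). Of the other named calls, each had 6 of 6 conventional mice on the same side of the germ-free mean. With the preset correlation 11 of 31 lists passed, with camera's estimated one 0, where 1 had an unadjusted p under 0.05, and fry called 5.

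**Figure D4:**
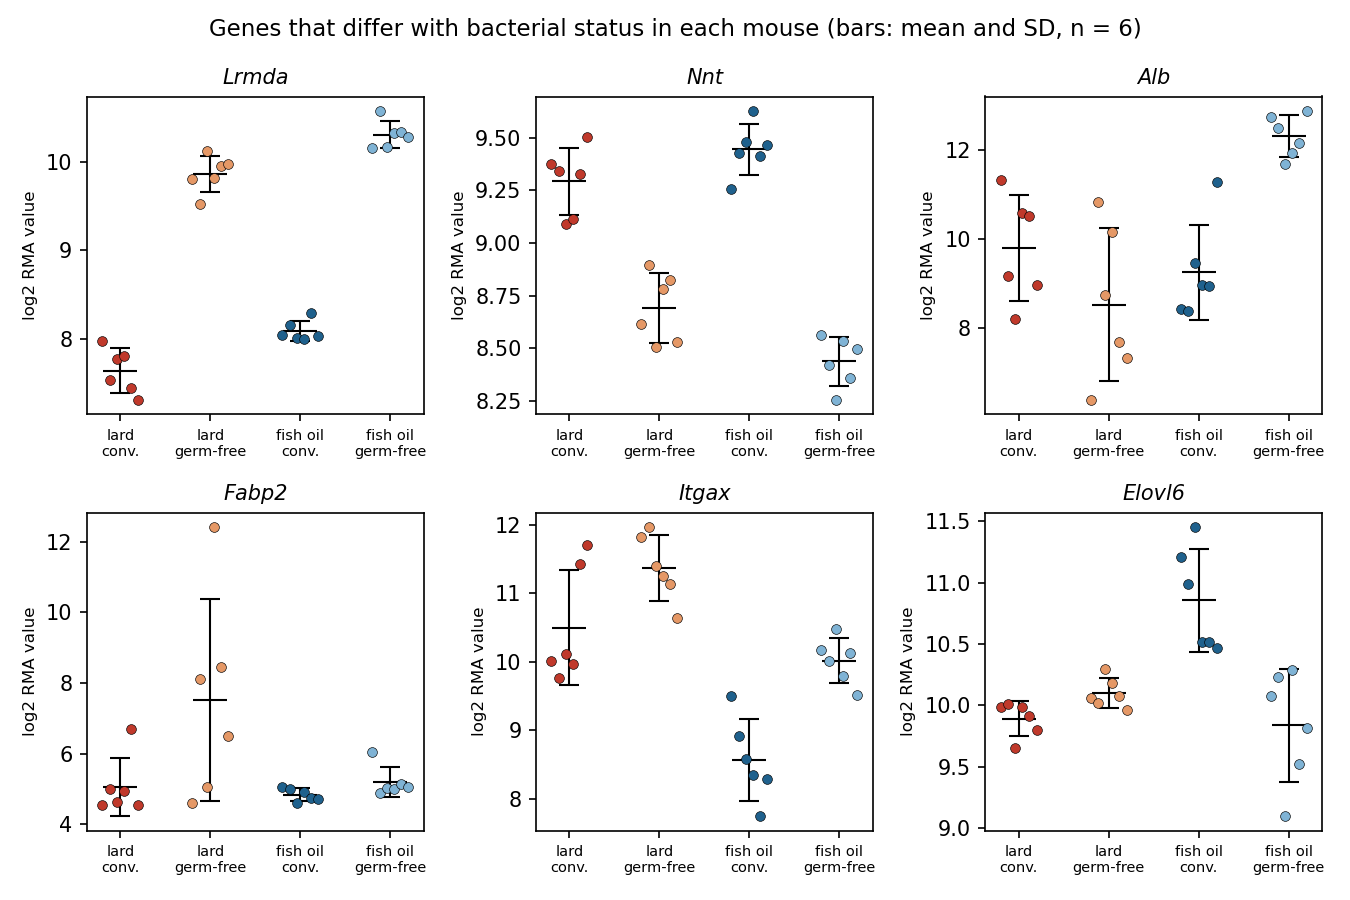
Log2 RMA values of 6 genes in each mouse (points), with the mean and SD of each group of 6 (bars). Lrmda is lower in all 12 conventional mice than in all 12 germ-free mice, whereas Alb is highest in fish oil-fed germ-free mice (12.31 ± 0.46) and Fabp2 is spread over the lard-fed germ-free mice (7.53 ± 2.86).

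The same question was put to fish oil-fed mice. Conventional mice had higher levels of 11 of 22 fatty acid synthesis, 9 of 20 cholesterol synthesis and 20 of 27 oxidative phosphorylation genes than germ-free mice. They had lower levels of 14 of 17 lipid-associated macrophage, 5 of 16 endothelial and 6 of 22 stress-response genes, and of liver transcripts. None of the 6 lists other than the liver transcripts passed with an estimated correlation (adjusted p from 0.288 to 0.384). Rasd1, a glucocorticoid-induced Ras protein, was higher by 2.12 ± 0.22 (SE, adjusted p = 2.9e-06), Gys2, glycogen synthase, by 1.38 and the fatty acid elongase Elovl6 by 1.02. The lipid droplet protein Cidea and the cytochrome oxidase subunit Cox8b, both of brown-like adipocytes, were higher by 1.20 each. Nnt, a mitochondrial transhydrogenase, averaged 9.44 ± 0.12 log2 in conventional and 8.44 ± 0.12 in germ-free mice (SD, n = 6; change 1.01, adjusted p = 5.3e-08), and Lrmda had a change of -2.21. Serpina1c had a change of -3.95, Fabp1, a liver and gut fatty acid-binding protein, of -3.17, Alb of -3.06 and Fgb of -2.71. With the liver covariate the change of Fabp1 turned to 0.39 (adjusted p = 0.647). Of the 25 liver transcripts, 23 were lower in conventional mice and 0 higher, with a median change of -1.55.

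A total of 2464 genes differed, 1425 higher and 1039 lower in conventional mice, and 361 of them by at least 1.5-fold. With each array centred on its median the split was 2757 higher and 701 lower, and with the liver transcript mean as a covariate 1636 genes differed. Of these 1636, 841 were among the 2464. Lipid-associated macrophage markers were lower in 14 of 17 and higher in 0, or 15 and 0 adjusted over the list alone (adjusted p = 0.322 with an estimated correlation). Atp6v0d2 had a change of -1.78, Gpnmb of -1.50, Itgax of -1.45 and Trem2 of -1.39 ± 0.29 (adjusted p = 0.0027), from 10.39 ± 0.31 in germ-free to 9.00 ± 0.62 in conventional mice. The call of Atp6v0d2 ended with the liver covariate (-1.93, adjusted p = 0.0503). Fatty acid synthesis and desaturation genes were higher in 11 of 22 and lower in 0, as they were adjusted over the list alone (adjusted p = 0.322 with an estimated correlation), with Scd2 at 0.90, Acly, ATP citrate lyase, at 0.85 and Fasn at 0.46; with the liver covariate Scd2 (0.62, adjusted p = 0.23) and Fasn (0.60, adjusted p = 0.0734) no longer passed. Cholesterol synthesis genes were higher in 9 of 20 and lower in 0, or 12 and 0 adjusted over the list alone (adjusted p = 0.322 with an estimated correlation), with Idi1 at 0.80 and Pmvk at 0.66. Oxidative phosphorylation genes were higher in 20 of 27 and lower in 0, or 24 and 0 adjusted over the list alone (adjusted p = 0.288 with an estimated correlation), with Ndufa4 at 0.54 and Ndufa5 at 0.51.

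Endothelial markers were lower in fish oil-fed conventional mice in 5 of 16 and higher in 0, or 10 and 0 adjusted over the list alone (adjusted p = 0.384 with an estimated correlation), with the vascular growth factor receptor Flt1 at -0.73 and Tie1 at -0.69, whose call ended with the liver covariate (-0.83, adjusted p = 0.0518). Immediate early genes, which respond within minutes to stimuli, were lower in 5 of 22 and higher in 0, or 9 and 0 adjusted over the list alone (adjusted p = 0.322 with an estimated correlation); Atf3 had a change of -1.24 and Dusp1 of -0.89. Cytokines and chemokines were lower in 4 of 33 and higher in 0, or 5 and 0 adjusted over the list alone (adjusted p = 0.368 with an estimated correlation), with Ccl3 at -1.50 and Il1a at -0.92. MHC class II genes were lower in 6 of 12 and higher in 0, or 6 and 1 adjusted over the list alone (adjusted p = 0.322 with an estimated correlation), with the protease Ctss at -1.07 and Cd74 at -0.34. Toll-like receptor genes were lower in 4 of 26 and higher in 0, the same adjusted over the list alone (adjusted p = 0.384 with an estimated correlation), and Nfkbia, the NF-kappaB inhibitor, had a change of -0.56. Clock genes were lower in 4 of 17 and higher in 1, or 6 and 2 adjusted over the list alone (adjusted p = 0.354 with an estimated correlation). Per1 and Per2 had changes of -0.95 and -0.88, and these calls ended with the liver covariate (-0.67 and -0.52, adjusted p = 0.123 and 0.179). Saa3 differed by 0.30 (adjusted p = 0.56), Lcn2 by -0.33 (adjusted p = 0.52), or by -1.56 with the liver covariate, which passed (adjusted p = 0.0189), Adipoq by 0.05 (adjusted p = 0.85) and Lep by -0.11 (adjusted p = 0.64). Each named gene past the threshold had 6 of 6 conventional mice on the same side of the germ-free mean. With the preset correlation 16 of 31 lists passed, with camera's estimated one 0, where 3 had an unadjusted p under 0.05, and fry called 14.

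Across the 19938 genes, the bacterial status effect with lard and that with fish oil, which share no mice, had a Pearson correlation of 0.263 (jackknife SE 0.0774, leaving out mice) and a Spearman correlation of 0.227. With the liver transcript mean as a covariate the Pearson correlation was -0.096. That fit has a single slope per gene. Mean liver values in conventional and germ-free mice were 6.74 and 6.45 log2 with lard, and 6.46 and 8.25 with fish oil. Errors of the slope thus enter both status effects with opposite signs, which by itself pushes their correlation down. A total of 542 genes were higher in conventional mice with both diets, where independent lists would share 125, and 134 were lower with both, where independent lists would share 77.7. Another 60 were called in opposite directions.

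The last comparison tested whether the effect of bacterial status differed between the diets, as the effect with lard minus that with fish oil. Interactions were positive in 8 of 33 cytokine and chemokine, 5 of 19 acute-phase and 8 of 12 MHC class II genes, and negative in 5 of 22 fatty acid synthesis genes. None of these lists passed with an estimated correlation (adjusted p = 0.645, 0.665, 0.224 and 0.665). The acute-phase genes counted include Fgb (3.29), which is also 1 of the 25 liver transcripts. Saa3 was higher in conventional mice by 1.94 with lard and differed by 0.30 with fish oil, an interaction of 1.64 ± 0.40 (SE, adjusted p = 0.015; 6 mice in each group). Interactions of the chemokines were 2.01 for Ccl8 and 1.27 for Cxcl10, of the cytokine Il1a 1.18, and of Lcn2 1.46 (adjusted p = 0.034); Ccl2 had 1.11 (adjusted p = 0.084). Ccl2 passed with array weights (1.21, adjusted p = 0.0265), with the replicate block (adjusted p = 0.0331), without mice 5 and 6 (1.31, adjusted p = 0.033) and with the liver covariate (2.48, adjusted p = 0.00175). The calls of Lcn2, Ccl8, Acaca and Tie1 each ended when any of several single mice was left out, with adjusted p up to 0.0632, 0.0583, 0.0666 and 0.0615. Those of Lcn2 (1.24, adjusted p = 0.0559) and Acaca (-0.636, adjusted p = 0.0659) also ended without mice 5 and 6. That of Tie1 also ended with the liver covariate (0.935, adjusted p = 0.0642). Liver transcripts had the largest interactions, at 5.42 for Serpina1c, 4.33 for Alb and 3.45 for Ahsg, fetuin-A, with 21 of the 25 past the threshold and a median of 1.74.

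A total of 1435 genes had an interaction, 561 positive and 874 negative. With each array centred on its median the split was 312 and 1688. Leaving out single mice gave 861 to 2070 genes, array weights 2526, the liver covariate 2326 and leaving out lard-fed conventional mice 5 and 6 2710. With the liver covariate 962 of the 1435 calls were kept. Without lard-fed germ-free mice 2, 4 and 5 the count was 225, and 13 of the 23 named calls ended, several with interactions about as large: Lcn2 1.47, Saa3 1.55, Inmt -1.52, H2-Ab1 0.51 and Tie1 0.73. MHC class II genes had positive interactions in 8 of 12, or 10 adjusted over the list alone, and negative in 0 (adjusted p = 0.224 with an estimated correlation), with H2-DMa at 0.57 and H2-Ab1 at 0.52. Cytokines and chemokines had them in 8 of 33, or 13 adjusted over the list alone, and negative in 0 (adjusted p = 0.645 with an estimated correlation). Of the Toll-like receptor genes 2 of 26 were positive, Nfkbia (0.58) and Ticam1 (0.47), and 2 negative, among them Map3k7 (-0.60), or 4 and 2 adjusted over the list alone, with no call for the list by camera (adjusted p = 0.449; 0.861 with an estimated correlation). Endothelial markers were positive in 2 of 16, or 7 adjusted over the list alone, and negative in 0 (adjusted p = 0.665 with an estimated correlation), with Tie1 at 0.78.

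Fatty acid synthesis genes had negative interactions in 5 of 22, or 7 adjusted over the list alone, and positive in 0 (adjusted p = 0.665 with an estimated correlation). Among them were Elovl6 at -1.22 ± 0.24 (adjusted p = 0.0044), the malic enzyme Me1 at -0.78 and Acaca at -0.80, whose call also ended with quantile normalization, the mean of probe sets and the replicate block. Gys2 had -1.63, Oxtr -1.55, Rasd1 and Inmt -1.51 each, and Acot2, an acyl-CoA thioesterase, -1.13. Oxidative phosphorylation genes had negative interactions in 4 of 27, or 5 adjusted over the list alone, and positive in 0 (adjusted p = 0.72 with an estimated correlation), with Atp5b, of ATP synthase, at -0.40. The list median of -0.03 turned to 0.11 without lard-fed conventional mice 5 and 6 (adjusted p = 0.893). Lrmda, named after its values were seen, had an interaction of -0.01. With the preset correlation 13 of 31 lists passed, with camera's estimated one 0, where 2 had an unadjusted p under 0.05, and fry called 2.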

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

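The tests of the patterns weighed here, and the lists of liver and intestinal transcripts, were chosen after the results were seen; the tests for far mice and for interactions were planned.

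A mouse lay far from the other 5 of its group in 14 of 355 combinations of a named gene and a group, and chance gives about 1 in 20. Fish oil-fed conventional mouse 6 accounted for 7 of them. It was lowest in Timp1 (6.768) and Saa3 (8.195) and highest in Cidea (9.732), in Fabp1 (7.633) and in the liver transcripts Alb (11.283), Fgb (8.339) and Ahsg (7.908), all in log2. Lard-fed conventional mouse 5 was highest in Fabp2 (6.686) and Zg16 (6.201), mouse 6 in Acot2 (9.276) and mouse 3 in Pfkl (9.957). Fish oil-fed germ-free mouse 2 was lowest in Fam13a (11.777), lard-fed germ-free mouse 3 in Lox (10.399) and lard-fed germ-free mouse 2 in Ebp (9.691).

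The effect of bacterial status differed between the diets in 34 named genes by limma's interaction test, each with an adjusted p under the threshold. With the status effect under lard above that under fish oil, immune and acute-phase genes had log2 differences of 0.565 (H2-DMa), 0.523 (H2-Ab1), 0.477 (Cd74), 0.474 (Ticam1), 0.581 (Nfkbia), 1.643 (Saa3), 1.459 (Lcn2), 2.014 (Ccl8), 1.27 (Cxcl10), 1.178 (Il1a) and 0.525 (Zbp1). Other positive differences were those of Tie1 (0.78) and Ebp (0.395), of the liver transcripts Serpina1c (5.415), Alb (4.329), Fgb (3.286) and Ahsg (3.455), and of Fabp1 (3.15), which is not in the liver list. Negative differences were found for the metabolic genes Acaca (-0.801), Lss (-0.715), Elovl6 (-1.225), Me1 (-0.781), Acot2 (-1.129), Gys2 (-1.632), Atp5b (-0.4), Cidea (-1.063), Nnt (-0.406), Asns (-0.339) and Inmt (-1.506). Ffar4 (-0.509), Oxtr (-1.555), Rasd1 (-1.509), Map3k7 (-0.596) and Entpd4 (-0.347) were negative as well. Of the probe sets with no gene symbol, which the main comparisons left out, 2011 of 12146 differed between lard and fish oil in conventional mice at an adjusted p under 0.05.

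Liver transcripts were higher in fish oil-fed germ-free mice than in the other 3 groups, with Alb at 12.31 ± 0.46 log2 (SD, n = 6) against 9.25 ± 1.07 in fish oil-fed conventional mice. Of the 25 liver transcripts, 23 were past the threshold, 1 is also in a fixed list, and 3 lay above the median gene in fish oil-fed conventional mice. A rise caused by germ-free status alone is argued against by the lard-fed mice, where the median change of the list, conventional over germ-free, was 0.326 (quartiles 0.118 to 0.513) in place of a negative value. Liver RNA in these samples is a candidate explanation: the excess over fish oil-fed conventional mice had a Spearman correlation of 0.922 across the 25 genes, which are not independent replicates, with the excess of lard-fed conventional mouse 1 over mice 2 to 6 of its group, where reassigning the folds of mouse 1 among the genes, which keeps their brightness, gave a median of 0.467 and at most 0.841 in 1000 trials. An effect of fish oil without microbes on the fat itself stays open, since fat cells that made these transcripts in liver proportions would give the same order.

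Lard-fed conventional mice 5 and 6 lay with the germ-free mice on the first principal component. That they were germ-free mice with the wrong label was tested first on genes that separate status: their median positions, with 0 at conventional mice 1 to 4 and 1 at the germ-free mean, were 0.832 and 1.047 over 20 genes, and 6 of 161 genes had both mice on the conventional side, against up to 8 for a pair of true germ-free mice, both as a wrong label predicts. A later test, chosen after these, argues against it: in Lrmda, the gene with the widest gap between the fish oil groups, the nearer mouse lay 14.61 within-group SDs from the germ-free mean, with 7.45 and 7.32 log2 against 7.55 to 7.98 in mice 1 to 4 and at least 9.53 in the germ-free mice. More macrophages in these mice may account for part of the pattern, as both macrophage lists lay at least 0.293 log2 above the highest of mice 1 to 4 in both. The genes of these lists are among those that place the mice on the component, so this is not separate support. A processing batch shared with the germ-free lard arrays cannot be told apart from more macrophages, since 242 probe sets separated these 8 arrays from the other 16 by over 0.3 log2, against at most 1 with any other pair of conventional lard-fed mice, and no batch is given in the sources used here.

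In 16 genes the values of all 12 conventional mice lay apart from those of all 12 germ-free mice, against at most 1 gene in 100 random splits within diets. The widest gaps were in Lrmda (1.23 log2), Entpd4 (0.27), Nnt (0.19) and Rab4a (0.18). By this choice of genes, lard-fed conventional mice 5 and 6 lay with the conventional mice in each. Nnt carries a deletion in a C57Bl/6 sub-strain. The design does not separate the mouse colony from bacterial status, and a genetic difference between colonies and an effect of the microbes both stay open and untested.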

How the results depend on the processing

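The alternatives without lard-fed conventional mice 5 and 6, without lard-fed germ-free mice 2, 4 and 5, and with the liver covariate were chosen after the data were seen; all others were planned. Median centring, quantile normalization, the mean of probe sets, the eBayes trend and the fits of only the groups compared left the total counts of genes and lists within 1.5 times the main ones, but median centring moved the direction of calls: 2757 higher in place of 1425 for status with fish oil, and 312 positive and 1688 negative in place of 561 and 874 for the interaction. Quantile normalization gave 4008 higher and 4002 lower for diet in germ-free mice, in place of 4072 and 5396. Total counts and correlations moved beyond that or beyond their spread are given here, and the cause was not tested unless the setting's construction shows it. At least 1.5-fold, a stricter threshold, left 1627 and 1985 genes for diet in conventional and germ-free mice, 294 and 361 for status with lard and fish oil, and 385 for the interaction. All probe sets, which are more tests, gave 14835 for diet in germ-free mice and 5053 for status with lard. Array weights gave 5033 for status with lard and 2526 for the interaction.

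With an estimated correlation camera called 1 list for diet in conventional mice and 0 in each of the other 4 comparisons, where 4, 1, 3 and 2 lists had an unadjusted p under 0.05 and fry called 15, 5, 14 and 2. By construction this widens the error of each list whose estimated correlation lies above the preset one, though not that of the eicosanoid list, estimated at 0.0079. The filter on low values left 5 lists for status with lard, and a correlation of the status effects of 0.35.

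Without lard-fed conventional mice 5 and 6, status with lard had 5079 genes and the interaction 2710 genes and 8 lists, the correlation of the diet effects was 0.631, and the median of the oxidative phosphorylation list in the interaction turned from -0.032 to 0.109 (adjusted p = 0.893). Without lard-fed germ-free mice 2, 4 and 5, diet in germ-free mice had 5278 genes, status with lard 177 and the interaction 225. Fewer mice explain part of this, but the other 19 choices of 3 of these 6 mice left 482 to 3302 genes for status with lard (median 1581) and 295 to 1962 for the interaction. With the liver covariate, status with fish oil had 1636 genes and the interaction 2326, of which 841 and 962 were among the main calls. The correlations of the status and diet effects were -0.096 and 0.477, which the single slope per gene pushes down by construction. Fabp1 with fish oil turned to 0.387 (adjusted p = 0.647). The covariate also gave calls: Lcn2 at -1.348 for diet in germ-free mice and -1.558 for status with fish oil, and Ccl2 at 0.936 for status with lard and 2.48 for the interaction.

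Leaving out each mouse in turn gave 5319 to 6683 genes and 16 to 20 lists for diet in conventional mice, 8067 to 9769 and 10 to 12 for diet in germ-free mice, 2253 to 4302 and 9 to 15 for status with lard, 1761 to 2752 and 13 to 16 for status with fish oil, and 861 to 2070 and 12 to 15 for the interaction. The interaction count was 861 without lard-fed conventional mouse 3, 909 without fish oil-fed conventional mouse 3 and 925 without lard-fed germ-free mouse 4. Correlations ranged from 0.687 to 0.761 for diet and from 0.219 to 0.3 for status. Of 182 named gene results past the threshold, 10 were lost without some single mouse: Rnase2a, Fabp2, Zg16, Sis, Gpr50 and Arntl for status with lard, and Lcn2, Ccl8, Acaca and Tie1 for the interaction. Under a planned setting 6 lost the call: Rnase2a, Fabp2, Zg16 and Sis in the two-group fit and with the eBayes trend, Arntl with the block, and Acaca with quantile normalization, the mean of probe sets and the block. Planned settings also called genes that had not passed: Ccl2, Itgax and Adgre1 for status with lard and Ccl2 for the interaction.

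The mouse numbers name different mice and do not pair them: 9 of 36 same-numbered pairs had deviations correlated above 0.1 (range -0.497 to 0.351), and 2 of 24 arrays correlated best with their own number. With the number as a block, the counts were 6020, 9253, 2968, 2294 and 1131 genes in the order of the report, the lists 19, 11, 11, 15 and 13, and the correlations 0.734 and 0.263. The number of arrays and low signals near background limit what can be seen: of simulated interactions of 0.5 log2, 49% were recovered.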

Other observations

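The splits of the mice were planned; the intestinal transcripts and the genes that keep the conventional and germ-free mice apart were looked at after the data were seen.

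Enzymes that make eicosanoids, the lipid mediators formed from omega-6 and omega-3 fatty acids, changed in both directions with diet. In conventional mice the thromboxane synthase Tbxas1 was higher with lard by 1.60 ± 0.19 (SE, adjusted p = 9.28e-07; 6 of 6 mice above the fish oil mean) and the prostaglandin D synthase Hpgds by 1.63, while the prostaglandin E synthase Ptges had a change of -1.06. In germ-free mice Tbxas1 and Ptges had changes of 1.54 and -0.90. Of the 19 genes of the list, 4 were higher and 4 lower with lard in conventional mice, or 5 and 5 adjusted over the list alone, and 7 and 5 in germ-free mice by both counts, with no call by camera in either (adjusted p = 0.788 and 0.313) and a call upwards by fry in germ-free mice (adjusted p = 0.0243). Of 25 oxidative stress genes, 5 were higher and 8 lower with lard in conventional mice, or 6 and 8 adjusted over the list alone, with no call by camera (adjusted p = 0.572), and in germ-free mice 6 and 7 by both counts (adjusted p = 0.798); the epoxide hydrolase Ephx1 rose by 0.94, and by 1.19 in germ-free mice. Among 22 unfolded protein and stress response genes, 7 were higher and 1 lower with lard in conventional mice, the same adjusted over the list alone (adjusted p = 0.0445, and 0.346 with an estimated correlation), with Atf3 at 1.65 and the asparagine synthetase Asns at -0.95. In germ-free mice 7 were higher and 7 lower, or 8 and 7 adjusted over the list alone, with no call by camera (adjusted p = 0.614). With fish oil, 6 of these 22 were lower in conventional than in germ-free mice and 1 higher, or 7 and 1 adjusted over the list alone (adjusted p = 0.000513, and 0.288 with an estimated correlation).

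Of 18 T cell markers 1 was higher with lard in conventional mice, Il7r, the interleukin-7 receptor (1.81; 1.24 in germ-free mice, and there 1.12 with the liver covariate, adjusted p = 0.091), and in germ-free mice 1 was higher and 2 lower, by both counts, with no call by camera in either (adjusted p = 0.596 and 0.798). B cell markers were higher in 3 of 15 and lower in 0 in conventional mice, and higher in 1 and lower in 8 in germ-free mice, by both counts, with no call by camera (adjusted p = 0.187 and 0.313). Neutrophil markers were higher in 2 of 13 and lower in 3 in conventional mice, and higher in 0 and lower in 5 in germ-free mice, by both counts, with no call by camera (adjusted p = 0.681 and 0.154) and 1 by fry in germ-free mice (adjusted p = 0.0129). Of 14 mast cell and eosinophil markers 1 was higher in conventional mice, or 0 adjusted over the list alone, and in germ-free mice 2 were higher and 1 lower by both counts (adjusted p = 0.964 and 0.52). The mast cell protease Cpa3 rose in germ-free mice by 1.92, or by 1.79 with the liver covariate (adjusted p = 0.0793). Pvalb, parvalbumin, a muscle calcium buffer, rose with lard by 2.17 in conventional and 1.45 in germ-free mice; of the 14 muscle markers 1 was higher and 1 lower in conventional mice, and 1 higher and 5 lower in germ-free mice, by both counts, with no call by camera (adjusted p = 0.48 and 0.435).

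Epididymis and testis markers were lower with lard in 1 of 15 in conventional and 3 in germ-free mice, in 0 of either adjusted over the list alone, with no call by camera (adjusted p = 0.191 and 0.221) and 1 by fry in germ-free mice (adjusted p = 0.0182). Progenitor and fibroblast markers were higher in 5 of 17 and lower in 1 in conventional mice, by both counts (adjusted p = 0.019, and 0.389 with an estimated correlation). In germ-free mice 7 were higher and 1 lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.0142, and 0.592 with an estimated correlation). Thermogenic adipocyte genes were lower in 5 of 16 and higher in 2 in conventional mice, and lower in 5 and higher in 1 in germ-free mice, by both counts, with no call by camera (adjusted p = 0.131 and 0.62) and a call downwards by fry in both (adjusted p = 0.00103 and 0.0473). Fatty acid oxidation genes were lower in 19 of 32 and higher in 2 in conventional mice, or 20 and 2 adjusted over the list alone (adjusted p = 0.00024, and 0.357 with an estimated correlation), and in germ-free mice lower in 9 and higher in 4, by both counts, with no call by camera (adjusted p = 0.798).

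Some effects of bacterial status had the same direction with both diets. Entpd4, a nucleotidase of the Golgi, had changes of -0.94 with lard and -0.59 with fish oil, and Pfkl, phosphofructokinase, Rab4a, an endosomal GTPase, and Wdfy1, an endosomal adaptor, had 0.45 and 0.49, 0.60 and 0.92, and 0.40 and 0.57, each in 6 of 6 mice. Nnt was higher in conventional mice by 0.60 with lard (adjusted p = 0.000182), and its interaction is given above.

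The 20 intestinal epithelium transcripts, of which 0 are in a fixed list, had a median change of -0.74 for conventional over germ-free mice with lard. Fabp2 was at 12.42 log2 in lard-fed germ-free mouse 4, 8.46 in mouse 5 and 8.11 in mouse 2, against 4.60, 5.06 and 6.51 in mice 1, 3 and 6. No explanation was tested.

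Other splits of the same mice, 100 for each comparison with the real one included, show whether chance can be excluded. For the counts of genes it can, down to the 1 in 100 that these splits reach, for each comparison of diet or of status. In each, 1 of 100 splits was as large, the real one, and not all possible splits were drawn. Diet had 6178 genes in conventional mice against at most 841 in the other splits, and 9468 in germ-free mice against 4138. Status had 3240 genes with lard against 2535, and 2464 with fish oil against 668. The interaction had 1435 against 1103, but its splits exchanged bacterial status within each diet. They remove the status effects along with the interaction, so chance is not excluded for the interaction alone. The margins of status with lard and of the interaction were narrow: without lard-fed conventional mouse 3 the counts were 2253 and 861, and without lard-fed germ-free mice 2, 4 and 5 they were 177 and 225, below the highest of the other splits, which hold all mice. For the counts of lists with camera's preset correlation, diet in conventional mice met the planned mark of fewer than 5 of 100 splits, though narrowly. There 4 of 100 splits gave 19 lists or more, the highest 20 and the median 12. This is 1 of 5 such tests, not adjusted for their number. The count also falls to 1 with an estimated correlation and to 16 without fish oil-fed conventional mouse 1 or lard-fed conventional mouse 2. Chance is thus not excluded for these lists. Nor is it for the other comparisons: 54 of 100 splits gave the 11 lists of diet in germ-free mice or more (highest 18), 36 the 11 of status with lard (18), 12 the 16 of status with fish oil (20) and 23 the 13 of the interaction (20). Their medians were 11, 9, 11 and 10 lists.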
